A study of Homo sapiens with 4 samples.

How the data were processed

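HOXB13 chromatin immunoprecipitation with sequencing in LNCaP cells was analysed from 2 deposited peak lists, 1 for the 2 lanes labelled GSK2879552 and 1 for the 2 lanes labelled vehicle. Groups were taken from the sample titles and descriptions. The treatment text is the same in all 4 samples and names the inhibitor, so the vehicle group rests on the titles and descriptions. The labels call the lanes of a treatment technical replicates and name 1 peak list for both lanes, so lanes could not be compared.

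The submitters' processing notes name BWA 0.7.2, SAMtools 0.1.18 and MACS2 2.1.2 and the builds hg19 and GRCh37, without role or order. Coordinates are hg19, as the sequence names in the lists show, and are given from 1. Each list had 1 row per peak. The deposited score was 10 times the −log10 q-value cut to a whole number in 100% of rows. The fold enrichment, a ratio of the pileup at the summit to the local background, is the authors' own value per peak and was used to describe, rank and filter peaks within a list and, with the p-value, to solve the pileup and background of each peak. The −log10 p-value and −log10 q-value per peak are the authors' deposited values at the summit, and the largest q-value was 0.0469 in the GSK2879552 list and 0.0500 in the vehicle list. The deposited summit offset in bp, counted from the start of the peak, gave the position of the summit. Use of an input control, read filters and calling options are not given in the sources used here. Pileups and local backgrounds were both whole numbers of tags, so neither had been scaled to the other, which is the case when the background is taken from the immunoprecipitated library itself. Tag ratios and expected numbers rest on that reading. Signal tracks were not analysed here.

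Peaks on chromosomes 1 to 22, X and Y entered the comparisons. Of the 68725 and 3722 deposited peaks, 676 and 215 on other sequences were left out. No peak interval occurred more than once. Pileup k and local background λ of each peak were solved from fold = (k + 1)/(λ + 1) and the Poisson −log10 p, taking the whole k that came within 0.001. Without the pseudocount of 1 a whole k was found for 0.450% and 0.800% of the 2000 peaks tried per list. The genome-wide background was taken as the commonest λ. Backgrounds above it were whole numbers of tags (within 0.05) in a 10 kb window at an extension of 139 bp for 100.0% of the GSK2879552 peaks concerned and at 100 bp for 100% of the vehicle peaks, which were also the smallest peak widths. The highest pileups, 278 and 199, were at or just below the ceiling of 278 and 200 that 1 tag per position and strand gives.

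Shares are given with exact 95% binomial intervals. Overlap of at least 1 bp was set against 1000 random placements of the vehicle peaks within their chromosomes (fixed seed), each chromosome taken from its start to the end of its last peak. Densities per Mb left out the long peak-free intervals. Bootstrap intervals of medians used 2000 samples. The bins of 1 Mb named in the text, the long peak-free intervals and the class of ordinary sites were chosen after the data were examined. Peaks named by fold enrichment followed a rule written in advance: the 5 peaks with the highest fold enrichment among vehicle peaks with a GSK2879552 peak, vehicle peaks without one, and GSK2879552 peaks without a vehicle peak, by coordinates where no annotation of the build was at hand.

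The expected number of GSK2879552 sites passing in the vehicle library was summed over sites as the Poisson chance that the scaled pileup reaches a −log10 p of 10 at the scaled background. The first version scaled every pileup by the background ratio of 6.31 (equal fold). The second shrank each pileup by the local slope of the pileup distribution and scaled the excess by the tag ratio of 4.54. The threshold of 10 replaced the lowest −log10 p of the vehicle list (4.62) after a first result had been seen, because the lower threshold ignores the least width of a peak. In simulated data with equal occupancy and a peak width rule, equal fold at a threshold of 4.6 gave 2.29 times the simulated number (2073 sites, spread 30 bp) and 2.18 times (2083 sites, spread 60 bp). At a threshold of 10 it gave 0.500 and 0.680 times, and the shrunken version 1.14 and 1.73 times. With 0.5 of the occupancy simulated in the vehicle library these became 5.30 and 7.90 for equal fold, and 12.1 and 20.1 for the shrunken version. The solver returned the known pileup for 100% of 2000 simulated GSK2879552 and 1993 vehicle peaks, and both overlap routines the known state for 100% of 300 intervals. The exact test matched on pileup gave p under 0.05 in 3% of 200 simulated sets without an effect and in 98.5% of 200 with 3 times the odds.

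Alternatives covered stricter thresholds, other definitions of overlap, lists of equal length and all sequences. Shares of peaks at promoters, motifs at summits and gene lists near peaks had been planned but were not run, since no genome or annotation of hg19 was used here. The gene table at hand names another assembly, so no peak was assigned to a gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.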

Results

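HOXB13 is a homeobox transcription factor of the prostate, and LNCaP is an established, androgen-sensitive prostate cancer cell line. HOXB13 binding was measured by chromatin immunoprecipitation and sequencing in LNCaP cells labelled as treated with GSK2879552, an inhibitor of the histone demethylase LSD1 (KDM1A), at 50 µM for 4 hours, or with vehicle. The comparison the design names is between the sites bound by HOXB13 with the inhibitor and those bound with vehicle. The 4 samples were 2 sequencing lanes of 1 library per treatment, which the labels call technical replicates, and the peaks of each treatment came as 1 list. There was thus no replicate of either treatment, so no value below has an error between cultures, and every interval and p-value compares lists or sites of these libraries and not the treatments. Intervals cover counting error only.

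The depth of each library was read from its own peaks. The pileup (overlapping extended tags) and local background behind each peak's deposited fold enrichment and p-value could be solved, with a whole-number pileup for 100% of the peaks of both lists within 0.001 on the −log10 p scale. The genome-wide background was 2.79 tags per position in the GSK2879552 library and 0.443 in the vehicle library, with tags extended to 139 and 100 bp. This comes to 201 and 44.3 tags per 10 kb, a ratio of 4.54. This is the ratio of tags in the libraries only if the background came from the immunoprecipitated library itself and not from a separate input, which is not given in the sources used here. Each fold enrichment is relative to the local background of its own peak.

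HOXB13 peaks were far more numerous in the GSK2879552 list than in the vehicle list. On chromosomes 1 to 22, X and Y of the hg19 build, the first held 68049 peaks and the second 3507, a ratio of 19.4. The ratio was 6.398 for peaks with a fold enrichment of at least 5, 18088 against 2827. The peaks covered 15649 kb and 521 kb. The median peak was 199 bp wide in the GSK2879552 list (quartiles 158 and 267) and 129 bp in the vehicle list (quartiles 101 and 166). The authors' fold enrichment at the summit had a median of 4.22 in the GSK2879552 list (quartiles 3.69 and 5.02) and 5.88 in the vehicle list (quartiles 5.19 and 6.85), each peak relative to the local background of its own library. The lowest pileup called was 10 in the GSK2879552 list and 5 in the vehicle list. At a lower background a peak needs a higher fold enrichment to pass. The medians and the ratio at a fold enrichment of at least 5 thus also reflect depth. The list with more peaks was the one with more tags, so peak number, depth and treatment differed together.

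The sites in the vehicle list were mostly sites of the GSK2879552 list as well. Of the 3507 vehicle peaks, 3199 overlapped a GSK2879552 peak by at least 1 bp, a share of 91.2% (exact 95% binomial interval 90.2 to 92.1). When the vehicle peaks were placed at random within their chromosomes, 0.869% overlapped on average and 1.43% at most, giving a permutation p of 0.001 (one-sided), the smallest that 1000 placements allow. The placements also fell in long stretches without peaks and did not keep to sequence where peaks can be called. A p-value from them, here or for the reverse overlap, thus does not show that the shared sites are sites of HOXB13 binding. The summits of overlapping peaks lay a median of 30 bp apart, and 68.0% lay within 50 bp. The share dropped to 50.4% when the GSK2879552 list was limited to as many peaks as the vehicle list by −log10 p, and to 29.8% when each peak had to cover at least 50% of the other.

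The shared sites with the highest fold enrichment in the vehicle list were on chromosomes 3, 13, 22 and 9. The first lay on chromosome 3 at 196625615 to 196625818, with a fold enrichment of 41.1 and a pileup of 119 over a local background of 1.92. It overlapped a GSK2879552 peak at 196625551 to 196625854 with a fold enrichment of 22.4 and a pileup of 151 over 5.78. A site on chromosome 13 at 110076487 to 110076732 had a fold enrichment of 30 in the vehicle list, and its partner at 110076409 to 110076766 had the highest fold enrichment of the GSK2879552 list, 25.7. The next were on chromosome 22 at 18717965 to 18718250 with 28.5, and on chromosome 9 at 42819046 to 42819214 with 28.4 and at 70076670 to 70076835 with 28.1. Their GSK2879552 partners had fold enrichments of 15.9, 16.1 and 16.7. In this order, the 5 sites had vehicle pileups of 119, 74, 58, 56 and 55 and GSK2879552 pileups of 151, 186, 85, 86 and 85. The genome-wide backgrounds differed 6.31 times, so pileup over that background was higher in the vehicle library at each. Ranking by vehicle fold enrichment favours such sites. All 5 counted as ordinary sites, as defined below, but no list of repeated or artefact-prone regions was used to filter peaks. Whether they are sites of HOXB13 binding was not tested.

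Most sites of the GSK2879552 list had no vehicle peak. A vehicle peak overlapped 3121 of the 68049 GSK2879552 peaks, a share of 4.59% (4.43 to 4.75), against 0.0449% on average and 0.0735% at most in the random placements (permutation p = 0.001, one-sided, the smallest possible). When the list was divided by fold enrichment into 10 classes of equal size, numbered from the lowest, the share was 0.558% (0.395 to 0.766) in class 3, 6.57% (5.99 to 7.18) in class 9 and 28.1% (27.0 to 29.2) in class 10. The share rose with each class from 3 to 10, while classes 1 and 2 lay above class 3 with 2.32% (1.98 to 2.71) and 0.720% (0.533 to 0.951).

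The GSK2879552 peaks without a vehicle peak that had the highest fold enrichment were on chromosomes 8, 7, 16, 15 and 20. They lay on chromosome 8 at 11031744 to 11032087 with a fold enrichment of 14.9, on chromosome 7 at 1337179 to 1337745 with 14.3, and on chromosome 16 at 22223325 to 22223682 with 14.2. The others were on chromosome 15 at 60078213 to 60078541 and on chromosome 20 at 58532561 to 58533019, both with 14.1. Their pileups were 78, 62, 77, 88 and 106. These sites were selected for the missing vehicle peak among many, so each is a description of this library.

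How many GSK2879552 sites would pass in a library of the vehicle's depth was computed from the solved pileups. Sites were called ordinary when no peak-free interval of at least 2.5 Mb lay within 2 Mb and the local background was under 5 times the genome-wide one, a division chosen after the data were examined. At 775 of 64774 ordinary GSK2879552 sites a vehicle peak reached a −log10 p of 10, a threshold that replaced a lower one after a first result had been seen. With equal fold over background in both libraries 850.1 would do so, a ratio of observed to expected of 0.912 (0.849 to 0.978), and with pileups shrunk for selection and scaled by tag number 2359. A ratio of 1 does not stand for equal occupancy. In libraries simulated with equal occupancy, under an assumed profile, the equal-fold expectation fell short of the simulated number and the shrunken one exceeded it. The ratio there thus lay above 1 with equal fold. The simulation had no ceiling and set every site at the genome-wide background, where 17.8% of the deposited GSK2879552 peaks lay. The observed 0.912 thus cannot be read against it. Observed numbers lay below the equal-fold expectation in each class under a pileup of 60. They lay above it at 60 to under 100, 285 against 272.2, and at 100 or more, 51 against 47.6. The observed share rose with the pileup of the GSK2879552 peak from 0.0504% (0.0308 to 0.0778) below a pileup of 20 to 2.28% (1.86 to 2.76) at 30 to under 40, 11.6% (10.3 to 13.0) at 40 to under 60 and 92.7% (82.4 to 98.0) at 100 or more. The ratio moved between 0.234 and 1.24 with the way the expectation was set, so the part of the difference in peak number beyond depth was not determined.

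**Figure D1:**
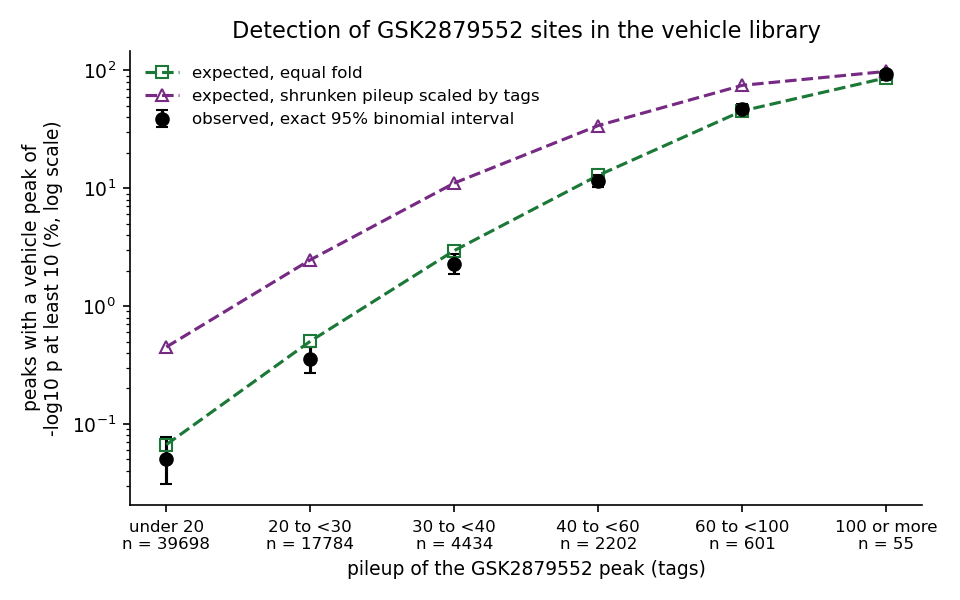
Share of ordinary GSK2879552 peaks overlapped by a vehicle peak with −log10 p of at least 10 (percent, log scale) against the pileup of the GSK2879552 peak, with exact 95% binomial intervals and both expectations. The observed share rises from 0.0504% below a pileup of 20 to 92.7% at 100 or more and lies below the expectation from shrunken pileups in each class.

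In the vehicle list, 308 peaks had no GSK2879552 peak. They were weaker than the others, with a median −log10 q of 3.41 against 4.59, a median pileup of 7 against 10 and a median width of 100 bp against 134 bp. Only 9 of them reached a −log10 q of 10, against 467 of the overlapped peaks. The highest fold enrichments among the 308 were on chromosome 10 at 42666854 to 42666999 with 10.2, on chromosome X at 58528512 to 58528658 with 8.0, and on chromosome 7 at 61982905 to 61983047 with 7.95. Next came chromosome 7 at 62031576 to 62031675 with 7.48 and chromosome X at 61884325 to 61884424 with 7.29. All 5 lay within 2 Mb of a long peak-free interval.

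Along the genome, both lists were sparse on chromosome X. The GSK2879552 list had a median of 26.0 peaks per Mb over the 24 chromosomes, from 5.37 on chromosome X to 29.7 on chromosome 21. The vehicle list had a median of 1.31, from 0.416 on chromosome X to 2.43 on chromosome Y. On chromosome Y, 90.6% of the vehicle peaks were not ordinary sites, and the ordinary sites came to 4.82 per Mb in the GSK2879552 list and 0.228 in the vehicle list. Chromosomes 2 and 13 had 16.0 and 18.1 GSK2879552 peaks per Mb. The median local background at GSK2879552 peaks equalled the genome-wide value on chromosome X, the lowest of the 24 chromosomes. It was 1.06 and 1.12 times that value on chromosomes 2 and 13, but 1.28 times on chromosome Y, with 14.0 GSK2879552 peaks per Mb. DNA copy number and tags per chromosome were not examined. A low density thus does not show that HOXB13 binds less on a chromosome. The share of vehicle peaks with a GSK2879552 partner lay between 85.2% (73.8 to 93.0) on chromosome 13 and 95.3% (91.2 to 97.8) on chromosome 2.

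**Figure D2:**
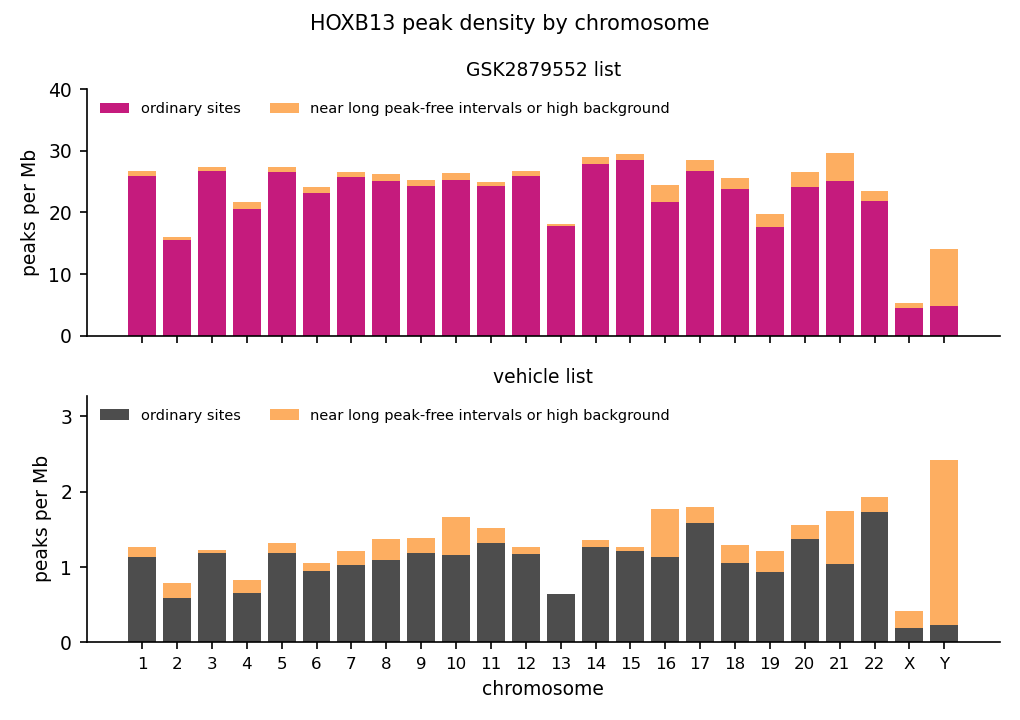
Peaks per Mb on each chromosome in the GSK2879552 list (upper panel) and the vehicle list (lower panel, another scale), with ordinary sites and sites near long peak-free intervals or of high local background stacked. Chromosome X has the lowest density in both lists, 5.37 and 0.416, and on chromosome Y most vehicle peaks are not ordinary sites.

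The bins with the most ordinary HOXB13 sites lay on chromosomes 11, 17, 12, 21 and 3. The 1 Mb bin with the most ordinary GSK2879552 peaks was on chromosome 11 from 23 to 24 Mb, with 72, and it held 7 ordinary vehicle peaks. Bins on chromosome 17 from 46 to 47 Mb, chromosome 12 from 54 to 55 Mb, chromosome 21 from 17 to 18 Mb and chromosome 3 from 71 to 72 Mb held 60, 59, 59 and 59 GSK2879552 peaks and 5, 12, 3 and 2 vehicle peaks. The bin on chromosome 12 was the one with the most ordinary vehicle peaks. It was followed by chromosome 11 from 48 to 49 Mb with 11 vehicle and 46 GSK2879552 peaks and by chromosome 8 from 128 to 129 Mb with 8 and 48. The vehicle peaks of the former had a median fold enrichment of 9.14 and a local background of 2.87 times the genome-wide one. On chromosome 12 these were 6.18 and 2.27. A long peak-free interval starts at 51.6 Mb on chromosome 11. The bin from 48 to 49 Mb is thus ordinary at the 2 Mb limit but not at the alternative of 5 Mb. The median bin with any ordinary peak held 24 in the GSK2879552 list and 1 in the vehicle list.

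Sites next to long peak-free intervals took a larger share of the vehicle list than of the GSK2879552 list. The GSK2879552 list had 28 peak-free intervals of at least 2.5 Mb, 18 of them between 3.0 and 3.4 Mb long. No genome of the build was used, so gaps of the assembly were not told apart from sequence without peaks. Such an interval thus does not show that HOXB13 was absent there. Whether the peaks beside the intervals are HOXB13 sites was not tested either. The 2 Mb on either side of these intervals made up 3.42% of the span with peaks. These flanks held 4.75% (4.59 to 4.91) of the GSK2879552 peaks and 15.9% (14.7 to 17.2) of the vehicle peaks. Local background of at least 5 times the genome-wide one was found at 0.757% (0.693 to 0.825) of the GSK2879552 peaks and at 9.92% (8.95 to 10.96) of the vehicle peaks. These shares depended on peak strength. Within the vehicle list the flank share rose from 2.28% in the lowest to 65.1% in the highest of 10 equal classes by −log10 q. Among the 100 peaks of highest pileup it was 91% in the GSK2879552 list and 92% in the vehicle list. For the 100 peaks of highest fold enrichment it was 5% and 52%. A shorter list of stronger peaks was thus not told apart from a difference between the libraries.

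At shared sites where the local background was high, it was relatively higher in the vehicle library. At shared sites with a GSK2879552 background of 2 to 5 times the genome-wide value, the vehicle's relative background was 0.952 times that of GSK2879552 (median of 687 pairs, bootstrap 95% interval 0.936 to 0.972). At 5 to 10 times it was 1.37 times (72 pairs, 1.27 to 1.48), and above that 1.71 times (164 pairs, 1.61 to 1.98). The bootstrap took pairs as independent, although neighbouring peaks can share tags of the same 10 kb window, so the intervals may be too narrow. A vehicle peak was called at 20.1%, 33.8% and 54.3% of the GSK2879552 peaks in these 3 classes, and the other sites did not enter. The local background of the densest vehicle bins varied. Chromosome 10 from 42 to 43 Mb held 52 vehicle peaks with a median local background of 26.7 times the genome-wide value, and chromosome 2 from 92 to 93 Mb held 35 with 55.5 times. Chromosome Y from 13 to 14 Mb also held 35, with 2.76 times, and chromosome 4 from 49 to 50 Mb held 27 with 10.1 times. Chromosome 16 from 46 to 47 Mb held 25 with 49.6 times, and chromosome X from 61 to 62 Mb held 24 with 4.37 times. In this order, these bins held 73, 39, 101, 88, 48 and 67 GSK2879552 peaks.

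**Figure D3:**
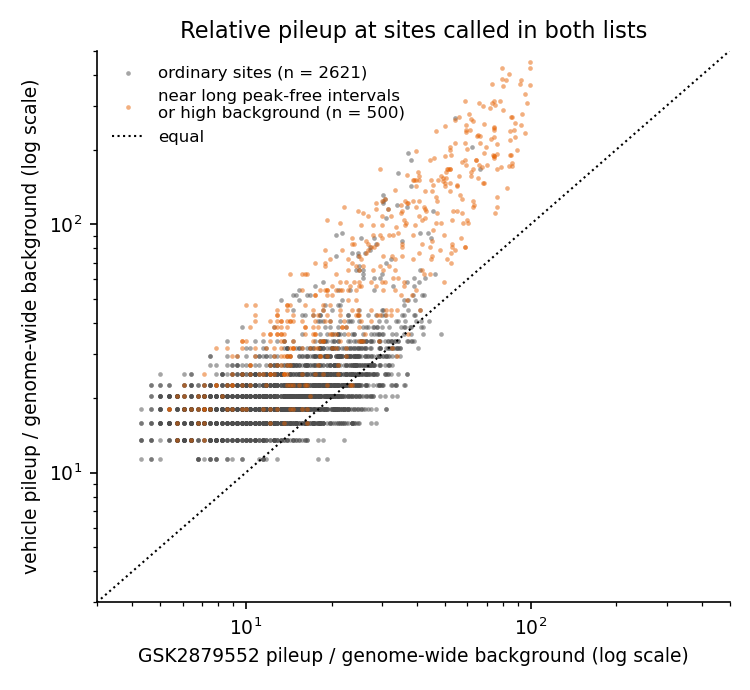
Pileup over genome-wide background in the vehicle library against that in the GSK2879552 library (both log scales) at the 2621 ordinary and 500 other GSK2879552 peaks with a vehicle peak, with a line of equal values. Vehicle values have a floor set by the calling threshold, GSK2879552 pileups end at 278 tags, and 86.1% of the ordinary and 98.8% of the other sites lie above the line.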

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

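All tests of explanations in this part were chosen after the result was seen.

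Outside the placed chromosomes, which the comparisons used, the GSK2879552 list held 676 peaks and the vehicle list 215. The number of peaks there was higher in the GSK2879552 list, but as a share of each list it was 0.984% (0.911 to 1.06) and 5.78% (5.05 to 6.57). Of the 215 vehicle peaks, 198 overlapped a GSK2879552 peak (92.1%, 87.6 to 95.3). A single unlocalised sequence of chromosome 9 held 100 and 65 of them, and the mitochondrial genome 5 and 11.

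The GSK2879552 list held 19.4 times as many peaks as the vehicle list. Fewer tags in the vehicle library may account for much of this: weak sites were missing and tall ones present, with 92.7% of the 55 ordinary sites of pileup 100 or more passing in the vehicle library. No list of artefact-prone regions was used to filter these 55 sites. Their presence thus does not show how HOXB13 sites of that height fare at lower depth. Lower enrichment in the vehicle library beyond its tag number stays open, since the same gradient would follow from it and the ratio of observed to expected sites, 0.912 with equal fold, was 0.329 with shrunken pileups scaled by tags. At 653 ordinary sites of pileup 60 to under 139 the median ratio of the vehicle's pileup over background to that of GSK2879552 was 0.971 to 1.12. It was 0.850 to 1.002 with the ceiling undone, each range depending on where sites without a vehicle peak are set. Pileup over background is not on the scale of tags. The backgrounds differed 6.31 times and the tags 4.54 times, with extensions of 139 and 100 bp. At narrow sites this can raise the vehicle's value, so a ratio near 1 does not show equal enrichment per tag. In simulated libraries of equal occupancy the equal-fold expectation was 0.50 and 0.68 of the simulated number. The ratio of observed to expected at equal occupancy thus lay above 1 there, under an assumed profile and with every site at the genome-wide background. The observed 0.912 thus cannot be read against it. An effect of GSK2879552 on HOXB13 binding stays open as well, untested, and cannot be told apart from a difference between libraries with 1 library per treatment.

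Sites near long peak-free intervals or of high local background took a larger share of the vehicle list. A shorter list of stronger peaks was not told apart from this. Of 319 sites that were not ordinary, with pileups in the range of the 653 ordinary ones above, 54.9% had a vehicle peak. The same median ratio was 1.36 (bootstrap interval 0 to 1.63) with the others set lowest and 4.04 with them set highest. The ratio was thus not shown to exceed 1 at these sites. At shared sites, a common depth factor was argued against by the ratio of relative backgrounds, 1.37 at 5 to 10 times the genome-wide value against 0.952 at 2 to 5 times. The bootstrap intervals lay apart but took neighbouring pairs as independent, and sites without a vehicle peak did not enter. Tags lost at the pileup ceiling of the deeper library would leave low pileups alone if every position could take tags. Where fewer positions can, the ceiling is lower, and this was not checked. Among GSK2879552 peaks of pileup 20 to under 40, a vehicle peak of −log10 p 10 was found at 4.40% (3.38 to 5.63) of 1363 sites that were not ordinary. At 22218 ordinary ones the share was 0.738% (0.630 to 0.860). At equal pileups 1.37% was expected at the former (exact test, two-sided, classes exchanged within each pileup value, p = 5.19e-17), whereas for any vehicle peak the share was 6.90% with 6.34% expected (p = 0.373), so the argument holds for strong vehicle peaks at low GSK2879552 pileups only. The exact test also took neighbouring sites as independent, so its p-values may be too small. A larger share of tags from repeated sequence in the vehicle library is a candidate explanation that cannot be told apart from an effect of treatment or culture, since the lists hold called peaks only, of which 5.78% lay outside the placed chromosomes in the vehicle list, and each treatment had 1 library.

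Of the vehicle peaks, 308 had no GSK2879552 peak although the GSK2879552 library was deeper. Sites near long peak-free intervals or of high background did not account for most of them, since these made up 13.96% (10.3 to 18.3) of the peaks without a partner and 17.8% (16.5 to 19.2) of those with one. The 2 shares were not compared at equal strength. Sites within 2 Mb of such an interval were 2.28% of the lowest and 65.1% of the highest of 10 equal classes by −log10 q, and peaks without a partner were weaker. Whether such sites were over-represented among them was thus not decided. Calls close to the threshold are a candidate explanation: 18.8% (14.9 to 23.3) of the lowest and 2.0% (0.808 to 4.08) of the highest of 10 equal classes by −log10 q had no partner. Sites bound by HOXB13 only without the inhibitor stay open, untested.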

How the results depend on the processing

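Peak numbers and overlap shares were recomputed under settings fixed before the data were examined, and settings named as added were chosen afterwards. The cause of a change was not tested unless it follows from the setting. With −log10 q of at least 5 the lists held 37314 and 1463 peaks, with at least 10 they held 11955 and 476, and with fold enrichment of at least 5 they held 18088 and 2827. The ratio of 19.4 became 25.5, 25.1 and 6.398. The share of vehicle peaks overlapped was 29.8% with reciprocal overlap of 50%, 80.8% with summits within 100 bp, 95.1% and 94.96% with −log10 q of at least 5 and 10 in both lists, and 50.4% with lists of equal length. The share of GSK2879552 peaks overlapped was 1.54%, 4.16%, 3.61%, 3.60% and 48.5% under these, 4.79% on all sequences and, as an added setting, 4.01% at ordinary sites. Without the pseudocount, whole pileups were found for 0.450% and 0.800% of peaks. The ratio of observed to expected vehicle peaks was set up after the data were examined. It was 0.234 in the setting tried first, with the lowest −log10 p of the vehicle list. The reported 0.912, with a threshold of 10, replaced it after that result had been seen. It was also put at 1.24 with a −log10 p of 15, at 0.329 with shrunken pileups scaled by tags and at 1.24 over all sites. The other 10 values, 4 of them added, stayed within the interval or 1.5 times of the reported one. No paired analysis was possible because each treatment had 1 library and 1 list for both lanes, which also ruled out leaving out a lane. Alternatives for promoters, motifs and gene lists were not run, with no genome or annotation of the build at hand. Depth limits the vehicle list: a missing peak there does not show that HOXB13 was absent.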

Other observations

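Among the 28 long peak-free intervals of the GSK2879552 list, the ones on chromosome 6 from 28629378 to 32241305 and on chromosome X from 3799173 to 7038612 were 3.61 and 3.24 Mb long. Chromosomes 6, 21, X and Y had 2 such intervals each. Neither held a vehicle peak. The alternate haplotype sequences of chromosome 6 in the build held 7 GSK2879552 peaks on 5 sequences and no vehicle peak was listed there. The only vehicle peak inside any of the 28 intervals lay in the interval on chromosome 3 from 90498996 to 93506190.

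The 5 bins with the most GSK2879552 peaks of any kind lay wholly or mostly within 2 Mb of a long peak-free interval by their peaks, and of the bins that came next, with 72 each, chromosome 21 from 10 to 11 Mb did and chromosome 11 from 23 to 24 Mb did not. Chromosome Y from 13 to 14 Mb held 101 GSK2879552 and 35 vehicle peaks, and chromosome 4 from 49 to 50 Mb held 88 and 27. Of the 100 peaks with the highest pileup, 97 in the GSK2879552 list and 99 in the vehicle list had a local background of at least 5 times the genome-wide one. Among ordinary sites with both peaks, the one ranked 3 by GSK2879552 fold enrichment was on chromosome 7 at 145694355 to 145694601, with 19.2 and a vehicle partner at 145694399 to 145694562 with 18.6. It was named after its values were seen.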
